A study of Homo sapiens with 57 samples.

How the data were processed

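The series holds 57 human samples, each a sorted cell population hybridised to 1 Affymetrix array of the 1-colour type. Per the labels, total RNA was purified with a PicoPure kit, amplified to cDNA and labelled with biotin. The values are on the log2 scale, as deposited by the authors in 1 table of 70523 probes, and per the submitters' processing notes they were made with RMA (background correction, quantile normalization and probe summary in its usual form) in Affymetrix Expression Console. The versions, filters and genome build are not given in the sources used here, so no positions are printed. The spreads of the columns differ (SD of 1.81 to 2.29), so the columns do not share 1 distribution. The highest value is 19.93, above 16, the log2 of what a 16-bit scanner can record, so the deposited scale is not that of raw scanner intensities and the size of the largest differences depends on it. No 2 columns were identical, and the highest correlation between 2 arrays was 0.989.

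Of the 70523 probes, 2995 were controls and 67528 transcript clusters, of which 23781 were assigned to 1 gene, 1543 to several and 42204 to none in the annotation used. Probes of 1 gene were kept, Y-linked genes, XIST and TSIX were left out, and the probe with the highest mean over all samples stood for its gene (22401 genes). Genes above the median of the array in at least 3 samples were tested (16768). Expression of neighbouring probes, splice variants and the transcript clusters without a gene was not analysed.

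Groups came from the labels: 5 blood subsets and epidermal LC of healthy donors, and the CD207 high, CD207 low, CD1a and CD3 sorts of lesions. The labels do not say how the gates of the sorts were set or whether the CD1a sort overlaps the CD207 sorts. The question of each comparison was taken from the series title. Donors are separate people per the labels, and sorts of 1 donor share that person. After group means were removed, the array of the same donor was the best match in 11 of 11 pairs of CD207 high and low cells, 5 of 7 pairs of CD207 high and CD1a cells and 2 of 10 pairs of CD207 high and CD3 cells.

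Differences were tested with limma 3.58.1 in R 4.3.3, with 1 model of group means over all 57 samples, moderated variances, 2-sided tests and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p under 0.05. Donor was not in that model. It was added as a fixed or random block as an alternative. Gene lists were tested with camera (limma), with the preset correlation of 0.01 and, beside it, an estimated correlation, adjusted over 43 lists. The lists, of cell type markers and pathways, held 613 genes, of which 555 were measured and 490 tested, and were fixed before the data were examined, as were the groups, the tests and most of the alternative settings.

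Named genes followed a rule fixed before the data were examined. It took the sort genes CD207, CD1A, CD1C, CD14, FCGR3A, THBD, CLEC9A, IL3RA, CD3D, CD3E and HLA-DQB2. It added, per comparison, the 8 largest rises and the 8 largest falls (5 and 5 between lesion sorts) among genes past the threshold whose samples did not overlap. Up to 4 members of each list with the smallest adjusted p completed it. Immunoglobulin and T cell receptor segments, HLA-DRB3, HLA-DRB4, HLA-DRB5 and genes with no official name were kept out of the largest changes. The genes named between CD207 high and CD207 low cells for their low p within donors, and the genes of the 3 patterns weighed in the closing section, were chosen after their values were seen.

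A signature of a healthy group was made of the genes higher in it than in each of the other 5 healthy groups (adjusted p under 0.05 in each contrast of a fit of the 18 healthy samples), ranked by the smallest difference, with at most 100 genes. Donor was not in that fit, and was added as a random block as an alternative after the data were seen. The recovery of a sample is the mean of its values over these genes, minus the mean of the other 5 groups, in percent of the same difference for the group itself. Differences between scores of 1 sample were tested by flipping the signs of the 11 donor differences in all possible ways, which gives an exact 2-sided p of at least 0.000977. Healthy samples left out of the signature were scored as a check. LC scored 60.4 to 104% and pDC 50.1 to 126%, while only 1 of 3 CD1c DC samples could be scored, at 22.1%. CD14 monocytes scored 41.3 to 114%, CD16 monocytes 52.2 to 112% and CD141 DC 58.5 to 118%. On values adjusted for the array set described below, all 3 CD1c DC samples were scored, at 41.5 to 129%.

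The pair of array sets was found from the spike-in controls bioB, bioC, bioD and cre, with no label behind it. The boundary of 11.2 lies in the gap between the sets. Array set as a covariate, each set alone, and values adjusted for the set were added as alternatives after the data were seen. The other alternative settings, written beforehand, were quantile normalization, median centring of the arrays, no filter or a filter at the 75th percentile, the mean of all probes of a gene, fits of 2 groups alone, trended and robust variances, array weights, a minimum difference of 1, donor blocks, and leaving out single samples or donors.

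The fits were tested on simulated data of the same design. At log2 differences of 0.5, 1, 2 and 4, CD207 high against CD1c DC recovered 18, 40, 82 and 100% of 50 changed genes with 0 false calls, and CD207 high against CD207 low 36, 58, 96 and 100%. With the array set as a covariate the same design of CD207 high against CD1c DC gave 46, 68, 94 and 100% with 12 false calls among 166, and CD207 high against LC 13 among 154. Donor as a block gave 12 among 183 for CD207 high against CD207 low. These are more than the 5% sought, so counts with the covariate or the block may run high. A list moved on purpose had an adjusted p of 1.6e-13 (camera) and 0 other lists passed. Errors were drawn separately for each gene, so this does not check the preset correlation. A recovery of 50% was read as 46.9% (LC) and 47.6% (CD1c DC). That simulation held no array sets or shared donors, and its CD1c DC signature had 64 genes against 3 in the data. It therefore does not check the CD1c DC score reported here. Figures were drawn with matplotlib 3.10.9.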

Results

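Gene expression was measured on 57 Affymetrix arrays, 1 per sorted cell sample, in cells from Langerhans cell histiocytosis (LCH) and from healthy donors. LCH is a neoplasm of the myeloid lineage whose lesion cells carry CD1a and CD207 (langerin) on their surface. The 39 lesion samples came from 11 donors, sorted as CD207 high cells (n = 11), CD207 low cells (n = 11), CD1a cells (n = 7) and CD3 T cells (n = 10). The 18 healthy samples were CD14 monocytes, CD16 monocytes, CD141 dendritic cells (DC), CD1c DC and plasmacytoid DC (pDC) from the blood of 3 donors, and Langerhans cells (LC) from the epidermis of another 3 donors, so that each healthy group had n = 3. Values are log2 signals, which ranged from 2.21 to 19.93, and 16768 genes were tested. The number of arrays limits the precision, most of all in the groups of 3.

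The sorted populations carried the RNA of the markers they were named for, with exceptions. CD207, the lectin that builds Birbeck granules, stood at 17.53 ± 0.99 (SD, n = 11) in CD207 high cells and 17.50 ± 0.85 (n = 3) in epidermal LC. It reached 15.22 ± 2.76 (n = 11) in CD207 low cells and 12.19 ± 3.74 (n = 7) in the CD1a sort, against 6.86 ± 0.33 (n = 3) in blood CD1c DC. CD1A, a lipid antigen presenter, lay between 16.09 and 16.37 in the means of the 3 lesion myeloid sorts and of LC, and at 8.57 ± 0.25 in CD1c DC. CD3D, a chain of the T cell receptor complex, stood at 12.23 ± 1.31 (n = 10) in the CD3 sort and 6.32 ± 1.09 in CD207 high cells. THBD, which encodes CD141, was 10.35 ± 0.86 in CD141 DC, little above CD14 monocytes (9.74 ± 1.54) and CD1c DC (9.13 ± 0.78), whereas CLEC9A, a marker of these DC, was 10.35 ± 0.75 in them and 6.23 ± 0.30 in CD1c DC. Other sort genes were FCGR3A (CD16), at 13.77 ± 1.41 in CD16 monocytes and IL3RA (CD123), at 14.28 ± 1.52 in pDC. The CD14 transcript had similar means in CD14 monocytes (6.93 ± 1.46) and CD1c DC (6.87 ± 1.58), and lower ones in CD141 DC (4.84 ± 0.11), pDC (4.84 ± 0.04) and LC (5.18 ± 0.27). HLA-DQB2, a class II chain found in LC, was 17.93 ± 0.46 in LC, 14.71 ± 1.86 in CD207 high cells and 10.03 ± 0.56 in CD1c DC.

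**Figure D1:**
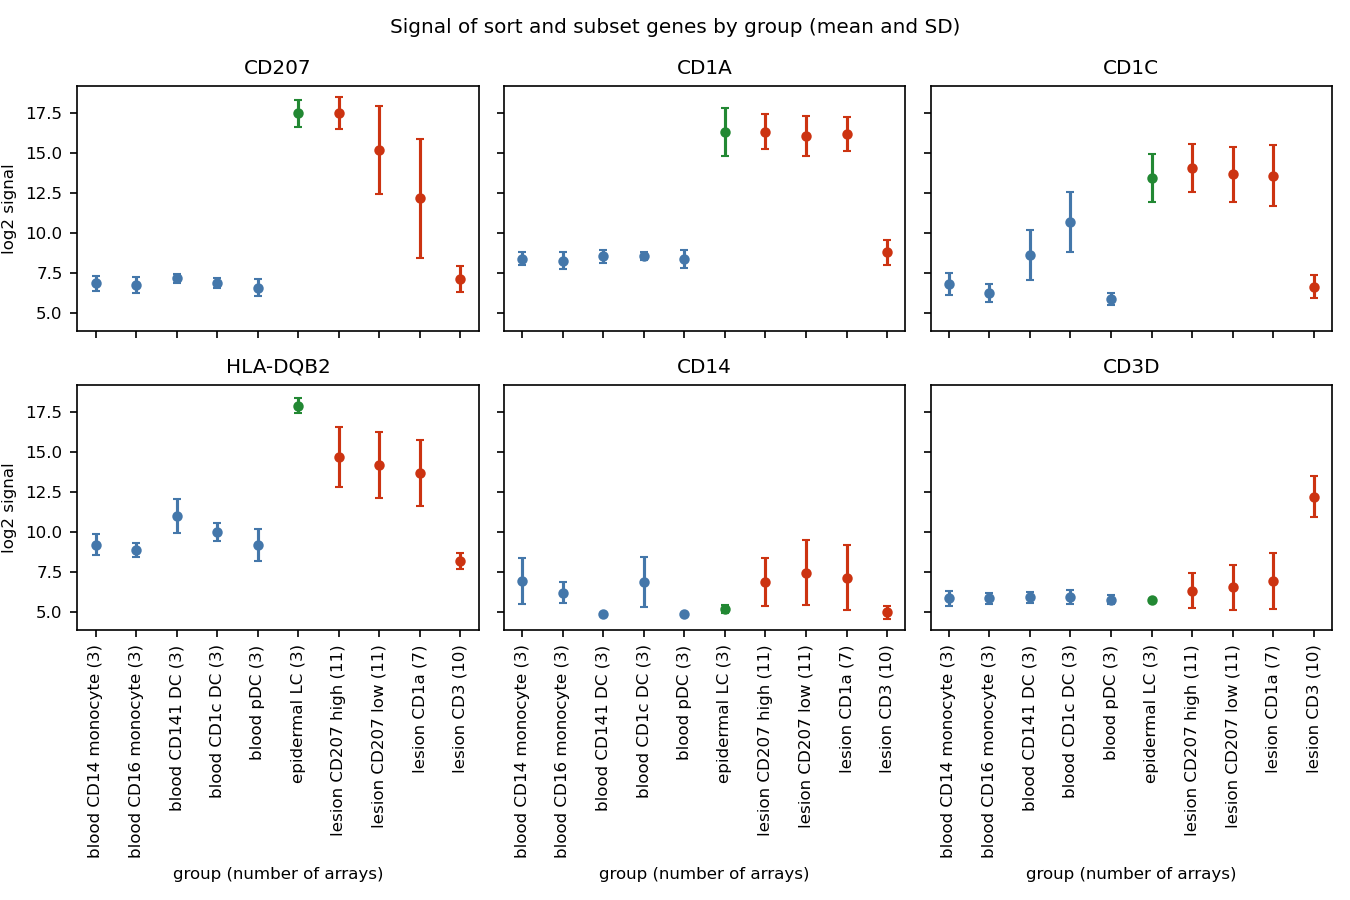
Mean log2 signal (vertical axis) of 6 genes in each group, with the number of arrays in parentheses and the SD as bars (blue, blood; green, epidermis; red, lesions). Mean CD1A was 16.09 to 16.37 in epidermal LC and the lesion myeloid sorts and 8.27 to 8.57 in the blood groups. CD207 varied most in the CD1a sort (12.19 ± 3.74), and CD1C was 14.09 in CD207 high cells and 10.69 in blood CD1c DC.

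The arrays also fell into a pair of sets that the labels do not name. The 4 bacterial spike-in transcripts added before hybridisation averaged 9.51 to 10.74 on 15 arrays and 11.57 to 12.75 on the other 42. The lower set held 1 of the 3 arrays of each blood group, 0 of the 3 LC arrays, 3 of 11 CD207 high, 3 of 11 CD207 low, 1 of 7 CD1a and 3 of 10 CD3 arrays. Within groups, the leading axis of variation carried 46.0% of the variance, and 85.3% of the variation along it lay between the sets. Counts are therefore given also with the set as a covariate and within the sets that hold more than 1 array of both groups. Within the lower set blood CD1c DC and the CD1a sort had 1 array each, which shows no spread, so only sizes of differences are given for them there.

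**Figure D2:**
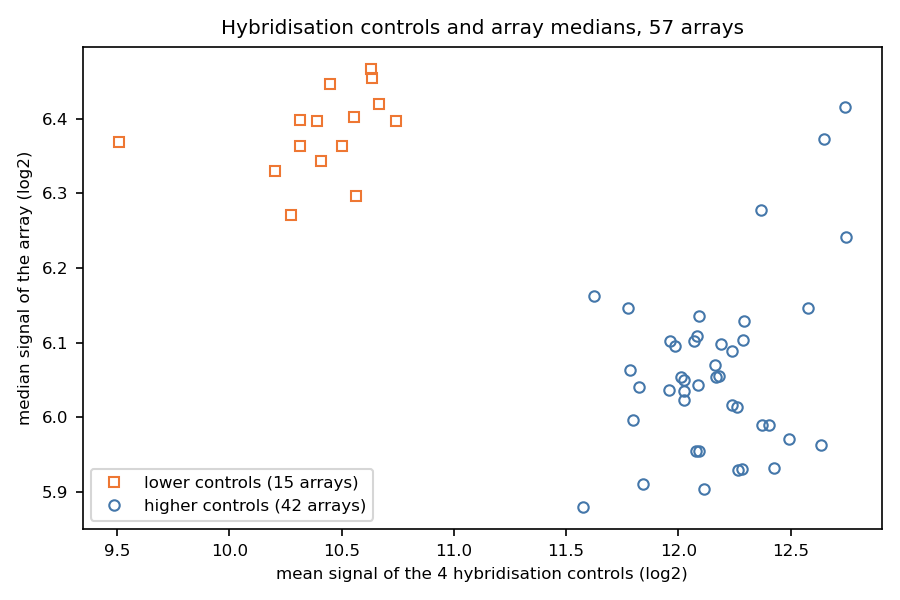
Mean log2 signal of the hybridisation controls (horizontal axis) against the median log2 signal of the array (vertical axis), 1 point per array. The 15 arrays with lower controls had medians of 6.27 to 6.47, and the 42 others 5.88 to 6.42.

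The series title names circulating CD1c DC as precursors of the lesion CD1a and CD207 positive cells, so the lesion sorts were first compared with blood CD1c DC. Most LC markers tested were higher in CD207 high cells, and most classical monocyte markers were lower. CD207 rose by 10.67 ± 1.24 (log2 difference ± SE; adjusted p = 5.8e-09), CD1A by 7.79 ± 0.63 (adjusted p = 1.9e-13) and HPGDS, the enzyme that makes prostaglandin D2, by 10.13 ± 0.51 (15.58 ± 0.52 against 5.44 ± 0.36; adjusted p = 7.5e-21). The elastase gene MMP12 (7.56), the myosin gene MYO1D (6.65), FCGBP (6.47), the myeloid receptor CLEC5A (5.99) and the gelatinase MMP9 (5.87) completed the 8 largest rises. OLR1, a scavenger receptor for oxidised lipoprotein, fell by 8.57 ± 0.51 (adjusted p = 2.6e-18), and lysozyme (LYZ) fell by 7.64, the chemokine receptor CXCR4 fell by 7.13, the innate receptor TREM1 fell by 6.43, the proteoglycan VCAN fell by 6.36 and the growth factor EREG fell by 5.79. VCAN-AS1 fell by 7.31 and the small nucleolar RNA SNORD75 fell by 6.77. CD1C itself was 3.40 ± 0.92 higher in the lesion cells (14.09 ± 1.50 against 10.69 ± 1.88; adjusted p = 0.0066), with overlapping samples, while FCGR3A (-2.12), THBD (-1.63) and IL3RA (-3.12) were lower. CD14 (-0.02), CLEC9A (-0.39), CD3D (0.38) and CD3E (0.12) did not pass the test.

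Of the 15 LC markers tested, 11 rose and 1 fell (11 and 1 when adjusted over the list alone, list adjusted p = 6.7e-13). CD1E rose by 5.82 and the tight junction gene CLDN1 by 4.87. The list also holds CD207, which names the sort. Of 15 classical monocyte markers, 0 rose and 11 fell (0 and 13 when adjusted over the list alone, list adjusted p = 1.0e-18). They included the lectin FCN1 (-4.15), the alarmin S100A12 (-4.06) and the receptor CSF3R (-2.68). In the blood CD1c DC themselves CD14 (6.87) and FCGR3A (8.25) stood near their means in CD14 monocytes (6.93 and 9.03). Healthy LC also had 7 of these 15 markers lower than CD1c DC. The fall is thus not particular to lesion cells, and the share that lies with the reference samples was not tested. In the TGF-beta pathway 7 of 14 genes fell and 0 rose (7 and 0 over the list alone; adjusted p = 1.5e-06), led by the signal transducer SMAD3 (-2.76), the activin chain INHBA (-2.73) and the inhibitors of differentiation ID3 (-1.91) and ID1 (-1.34). These 3 lists also passed with an estimated correlation between genes, with adjusted p of 0.0099, 0.0054 and 0.027. The other 7 lists that passed did not. With the array set as a covariate 7 of 43 lists passed, instead of 10. Among transcriptional outputs of MAPK/ERK signalling, the pathway that is mutated in LCH, 8 of 18 rose and 1 fell (10 and 1 over the list alone; adjusted p = 0.0015, and adjusted p = 0.085 with an estimated correlation). They included the feedback inhibitors SPRED1 (4.10) and SPRED2 (1.91), the cyclin CCND1 (3.03) and the transcription factor ETV5 (2.65). SPRED1 also belongs to the signature of healthy LC, so its rise over CD1c DC is not particular to lesion cells. Of 19 proliferation genes, 12 rose and 0 fell (15 and 0 over the list alone; adjusted p = 1.8e-06, and adjusted p = 0.40 with an estimated correlation), among them TYMS (2.75), TPX2 (1.95), CCNB1 (1.48) and MCM4 (0.70). In the CD1 family CD1A, CD1E and CD1C rose and CD1D fell by 0.84 (adjusted p = 0.0032, and adjusted p = 0.24 with an estimated correlation).

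Of 17 chemokines, CCL2 rose by 3.73 and the neutrophil attractants CXCL2 (-3.22), CXCL1 (-1.99) and CXCL3 (-1.50) were lower (list adjusted p = 0.031, adjusted p = 0.28 with an estimated correlation and adjusted p = 0.065 with the array set as a covariate). The 14 markers of CD1c DC went both ways: 5 rose, such as PKIB (2.93) and S100B (2.29), 2 fell, such as the cytokine receptor FLT3 (-3.54), and the list did not pass (adjusted p = 0.26). Markers of T cells (15 genes; adjusted p = 0.97), B and plasma cells (7 genes; adjusted p = 0.98) and endothelium (6 genes; adjusted p = 0.67) did not pass as lists. The matrix genes (6 rose and 3 fell of 18) did not pass as a list (adjusted p = 0.26) although MMP12, MMP9, the urokinase PLAU (3.33) and SPP1, osteopontin (5.69), rose.

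**Figure D3:**
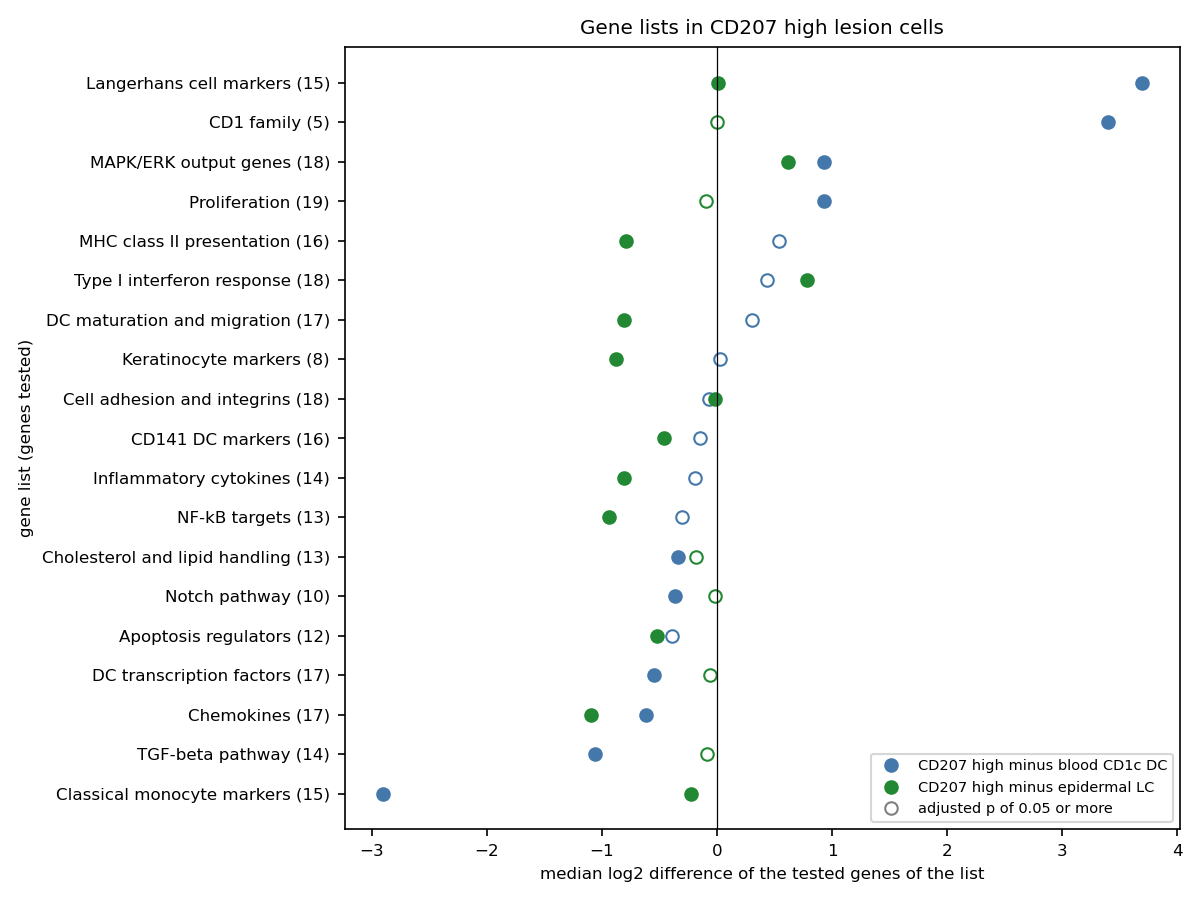
Median log2 difference (horizontal axis) of each gene list with an adjusted p under 0.05 in at least 1 of the comparisons of CD207 high cells with blood CD1c DC (blue) and with epidermal LC (green); open circles did not pass. LC markers had a median of 3.70 against CD1c DC and 0.01 against LC.

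In total 2541 of 16768 genes passed, 1268 higher and 1273 lower (limma, 2-sided, 11 against 3 samples), and 1536 of them differed by at least 1 on the log2 scale. Samples of the groups did not overlap for 1591 genes, or 9.49%, where chance gives 0.549%. With the array set as a covariate 3975 genes passed. Within the 42 arrays with higher controls 3173 passed. CD207 differed by 11.20 in the higher set and by 9.33 from the 1 CD1c DC array of the lower set, HPGDS by 10.52 and 9.24, and VCAN by -7.98 and -3.02. The count dropped to 1489 without CD1c DC replicate 1 and to 1279 without replicate 2. Only 3 arrays stand for the blood subset, and the cause of the drop was not tested.

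The other myeloid sorts of the lesions were compared with CD1c DC in the same way. In CD207 low cells HPGDS rose by 9.60, CD207 by 8.35, MMP12 by 8.62, CD1A by 7.52, SPP1 by 7.16, MMP9 by 6.40, MYO1D by 6.33 and FCGBP by 6.04, while OLR1 fell by 8.17, VCAN-AS1 fell by 7.08, VCAN fell by 6.27, TREM1 fell by 6.20, LYZ fell by 6.14, CXCR4 fell by 6.07, the histone gene H2BC10 fell by 5.93 and EREG fell by 5.28. In the CD1a sort HPGDS rose by 9.61, SPP1 by 7.88, CD1A by 7.61, MMP12 by 6.91, MMP9 by 6.79, MYO1D by 6.17, FCGBP by 5.86 and the mucin-like gene PARM1 by 5.70. OLR1 fell by 7.96 in that sort, TREM1 fell by 6.28 and CXCR4 fell by 5.99, with 3 small nucleolar RNAs (SNORD75, SNORD12C and SNORD41) among the 8 largest falls. LC markers rose in both sorts (11 up and 1 down of 15 in each, adjusted p = 4.0e-12 and 5.0e-10) and classical monocyte markers fell (10 and 9 of 15, adjusted p = 1.6e-16 and 1.9e-16). With the array set in the model and an estimated correlation, LC markers had camera adjusted p = 0.047 in CD207 low cells and 0.14 in the CD1a sort. MAPK/ERK output genes passed in both sorts, with 8 up and 1 down of 18 in CD207 low cells (adjusted p = 0.00022) and 3 up and 0 down in the CD1a sort (adjusted p = 0.0064). An estimated correlation gave camera adjusted p = 0.039 in CD207 low cells and 0.18 in the CD1a sort. With the array set in the model as well, these were 0.10 and 0.36.

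For CD207 low cells 2088 genes passed, 887 higher and 1201 lower (3565 with the array set as a covariate and 2792 within the higher set). For the CD1a sort 1874 passed, 746 higher and 1128 lower (3535 with the covariate and 2723 within the higher set). The split between rises and falls in the CD1a sort moved with the scaling, from 39.8% higher to 25.5% higher (286 higher and 837 lower) after each array was centred on its median. That of CD207 low cells moved from 42.5% to 32.6% higher (420 higher and 868 lower). That of CD207 high cells moved from 49.9% to 41.0% higher (644 higher and 927 lower). Without CD1c DC replicate 1 or 2 the counts were 1169 and 941 for CD207 low cells and 984 and 842 for the CD1a sort.

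How far the lesion cells carried the signature of each healthy subset was then scored in percent, where 0 is the mean of the other healthy groups and 100 the subset itself. CD207 high cells recovered 70.6 ± 15.1% (SD, n = 11) of the epidermal LC signature, with 78.2% on the arrays with higher controls and 50.3% on the others. They recovered 2.99 ± 7.08% of the CD14 monocyte, -5.67 ± 4.34% of the CD16 monocyte, 9.78 ± 8.14% of the CD141 DC, 1.35 ± 3.05% of the pDC and -2.42 ± 13.7% of the CD1c DC signature. The LC signature reached 65.5 ± 17.7% in CD207 low cells, 60.7 ± 16.7% in the CD1a sort and 5.96 ± 5.05% in CD3 cells. The CD1c DC score was lower than the LC score by 73.0 points in the mean (mean difference -73.0, higher in 0 of 11 donors; adjusted p = 0.00488, exact sign-flip permutation test over donors, 2-sided, 5 differences). It was also lower than the CD141 DC score (-12.2, higher in 2 of 11 donors; adjusted p = 0.0195), and did not differ past the threshold from the CD14 monocyte (-5.41; adjusted p = 0.438), CD16 monocyte (3.25; adjusted p = 0.600) and pDC scores (-3.77; adjusted p = 0.499).

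These blood scores rest on few genes: 3 for CD1c DC, 7 for CD141 DC, 12 for CD14 and 35 for CD16 monocytes, against 100 each for pDC and LC. The 3 CD1c DC genes were MIR3143, RNF151 and TCTA. CD1C was not among them, and FCER1A was in the LC signature. The CD1c DC score on deposited values, and each difference taken from it, therefore says little about CD1c DC identity. The LC signature held CD207 and CD1A, which name the lesion sorts. It also held keratins (KRT1 and KRT10), cell cycle genes such as MKI67 and TOP2A, and maturation genes such as CCL22 and LAMP3. The LC score is therefore not a measure of LC identity alone. A gene as high in LC as in CD1c DC could not enter the CD1c DC signature. The gap between the CD1c DC and LC scores therefore cannot decide whether lesion cells derive from CD1c DC. The CD141 DC signature also scored 36.6 ± 6.42% in the CD3 sort, so that it did not mark DC alone. With the array set removed from the values first, the CD1c DC signature had 39 genes and a score of 4.00 ± 10.98% in CD207 high cells, and the difference turned to 10.9 against CD14 monocytes (adjusted p = 0.0374), 3.21 against CD141 DC (adjusted p = 0.338) and 1.62 against pDC (adjusted p = 0.604; exact sign-flip permutation tests). The difference kept its sign at 11.2 against CD16 monocytes (adjusted p = 0.0220) and at -66.9 against LC (adjusted p = 0.00488; exact tests of the same kind), so that 3 of the 4 differences between blood subsets changed sign in this version. With signatures made from the 5 blood subsets alone, on the same adjusted values, the difference was -12.9 against CD141 DC (higher in 1 of 11 donors; adjusted p = 0.00586), 8.80 against CD14 monocytes (adjusted p = 0.00911), 17.2 against CD16 monocytes (adjusted p = 0.00586) and 3.86 against pDC (adjusted p = 0.117; exact tests over 4 differences). Healthy LC scored 52.6 ± 9.27% on this CD141 DC signature and -11.8 ± 9.60% on the CD1c DC one, so a lower CD1c DC than CD141 DC score is not particular to lesion cells. The sign-flip tests cover the spread among the 11 lesion donors and take the signatures as fixed. On adjusted values, left-out CD14 monocytes scored 53.5 to 122%, CD16 monocytes 64.3 to 110% and CD1c DC 41.5 to 129% on their own signatures. These ranges are wider than the differences between blood subsets, and the p-values do not cover them. The 5 blood subsets shared 3 donors. With donor as a random block in the signature fit, the CD1c DC signature had 10 genes, and the difference was 6.87 against CD14 monocytes (adjusted p = 0.291), 9.11 against CD16 monocytes (adjusted p = 0.0366), -1.98 against CD141 DC (adjusted p = 0.605), 3.09 against pDC (adjusted p = 0.435) and -67.5 against LC (adjusted p = 0.00488). In that version CD3 cells scored 10.4 ± 9.20% for CD1c DC, -14.8 ± 4.41% for CD14 and -1.63 ± 5.25% for CD16 monocytes. CD207 high cells scored 3.43 ± 11.6%, -3.43 ± 5.69% and -5.67 ± 7.15%. A CD1c DC score above the monocyte scores was thus not particular to lesion myeloid cells.

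**Figure D4:**
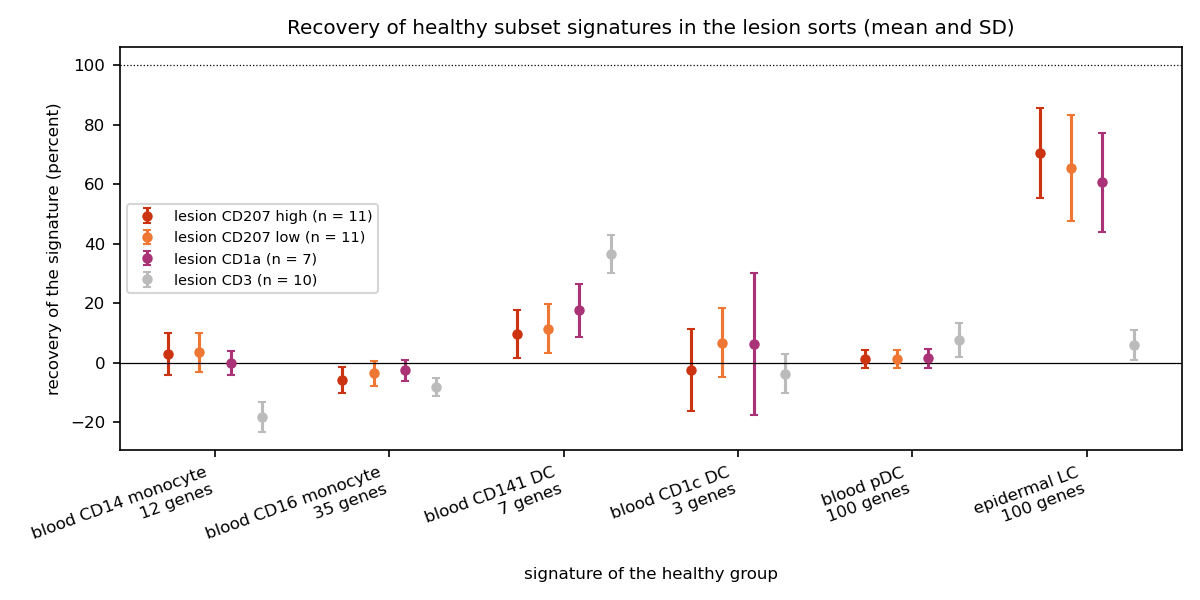
Recovery of each healthy signature in percent (vertical axis; 0, mean of the other healthy groups; 100, the subset itself) in the 4 lesion sorts, as mean and SD over donors. The LC signature stood at 70.6% in CD207 high cells and 5.96% in CD3 cells, and the CD1c DC signature of 3 genes at -2.42% in CD207 high cells.

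Epidermal LC are the healthy cells that share CD1a and CD207 with the lesions. CD207 (0.03 ± 1.24) and CD1A (0.00 ± 0.63) did not differ between CD207 high cells and LC past the threshold, at 17.53 against 17.50 and 16.37 against 16.36. The membrane protein gene EMP1 rose by 3.89 ± 0.50 in the lesion cells (13.86 ± 0.69 against 9.97 ± 0.33; adjusted p = 2.2e-07), with the exchange factor gene PLEKHG1 (3.88), the phosphatase PTPN13 (3.80), the glypican GPC6 (3.42), GPC6-AS1 (3.40) and the methyltransferase SMYD3 (3.41). NCF1B (3.79) and NCF1C (3.44) also rose, but they are near copies of NCF1, and whether the probes separate them was not tested. The chemokine CCL22 fell by 7.70 ± 0.97 (10.66 ± 1.57 against 18.36 ± 0.83; adjusted p = 1.1e-07) and E-cadherin (CDH1), which anchors LC to keratinocytes, fell by 6.04 ± 0.38 (5.68 ± 0.24 against 11.72 ± 2.49; adjusted p = 1.0e-16). CDH1 in the lesion cells lay below the medians of the arrays, as HPGDS did in CD1c DC, so background limits the size of such differences. LGALS2 fell by 6.03, CLIC2 fell by 5.94, LYZ fell by 5.61, CLIC4 fell by 5.18, the antigen presenter CD1B fell by 5.00 and OLR1 fell by 4.87.

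DC maturation genes were lower in the lesion cells: 6 of 17 fell and 0 rose (9 and 0 when adjusted over the list alone; list adjusted p = 1.8e-09), among them CCL22, LAMP3 (-3.70), the costimulator CD40 (-2.43) and the tryptophan-degrading enzyme IDO1 (-2.01). Of 16 markers of CD141 DC, 5 fell and 0 rose (8 and 1 over the list alone; adjusted p = 3.4e-06), led by the nuclease DNASE1L3 (-2.79), IDO1 and the transcription factor IRF8 (-3.16). Of 8 keratinocyte markers, 5 fell and 0 rose (5 and 0 over the list alone; adjusted p = 3.4e-10), led by the keratins KRT1 (4.94 ± 0.17 against 7.41 ± 1.22) and KRT10 (5.93 ± 0.27 against 8.28 ± 1.42). MAPK/ERK output genes were higher (2 rose and 0 fell of 18, 3 and 0 over the list alone; adjusted p = 1.0e-04), with SPRY4 (0.89) and MYC (2.01) past the threshold. These 4 lists passed also with an estimated correlation (adjusted p of 0.0023, 0.0044, 0.002 and 0.03 in this order). With the array set in the model as well, the MAPK/ERK list had adjusted p = 0.060. Immediate early and dissociation genes, which share 2 genes with it, had a median of 0.39 (16 genes; adjusted p = 0.17, and adjusted p = 0.0030 with the array set as a covariate).

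The LC markers as a list passed downward (0 rose and 5 fell of 15; adjusted p = 0.0096, and adjusted p = 0.58 with an estimated correlation), although their median was 0.01 and their mean -0.82. The call was lost with the array set as a covariate (adjusted p = 0.085) and in the higher set alone (adjusted p = 0.33, median 0.37), the set that held all LC arrays. In this comparison 13 of 43 lists passed, and 9 with the array set as a covariate. The 5 that fell were CDH1, the receptor kinase AXL (-3.98), EPCAM (-2.53), CLDN1 (-2.75) and HLA-DQB2 (-3.21; adjusted p = 0.048). Class II presentation (0 rose and 3 fell of 16; adjusted p = 0.00041, and adjusted p = 0.58 with an estimated correlation) and NF-kB targets (0 and 3 of 13; adjusted p = 0.00039, and adjusted p = 0.49 with an estimated correlation) were lower, with HLA-DOB (-2.21), the thiol reductase IFI30 (-3.78) and CD40 as examples. Of 17 chemokines 1 rose and 4 fell (adjusted p = 0.0039, and adjusted p = 0.17 with an estimated correlation). CD2, an adhesion receptor of T cells and some DC, was 3.32 ± 0.81 higher in the lesion cells (9.70 ± 1.64 against 6.38 ± 0.19; adjusted p = 0.0069), and PECAM1 2.83 higher (adjusted p = 0.0052).

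In all, 741 genes passed, 215 higher and 526 lower (limma, 11 against 3 samples; 494 with a difference of at least 1), and 931 genes, or 5.55%, had groups that did not overlap, where chance gives 0.549%. With the array set as a covariate 1475 passed (652 higher, 823 lower), and within the higher set 1328. The lower set held 0 LC arrays and gave no value. Leaving out LC replicate 1 or 2 lowered the count to 374 and 415.

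The difference between healthy LC and blood CD1c DC put these values in context. LC had CD207 higher by 10.64 ± 1.56, MMP12 by 9.26, HPGDS by 8.50, HLA-DQB2 by 7.90, CD1A by 7.79, CLDN1 by 7.62, CLEC5A by 7.33 and LINC00515 by 7.16. VCAN-AS1 fell by 7.51, VCAN fell by 6.45, TREM1 fell by 6.44 and H2BC10 fell by 5.96, next to the small RNAs SNORA48 (-5.98), SNORD75 (-5.78), SNORA24 (-5.78) and MIR3143 (-5.73). LC markers rose (11 of 15, 0 fell; adjusted p = 9.5e-23), classical monocyte markers fell (7 of 15; adjusted p = 1.3e-11), and DC maturation (7 of 17; adjusted p = 4.1e-07) and keratinocyte genes (4 of 8; adjusted p = 2.3e-07) rose. The proliferation list passed here as well (7 rose of 19; adjusted p = 5.0e-06, and adjusted p = 0.50 with an estimated correlation). In total 1329 genes passed, 773 higher and 556 lower (limma, 3 against 3 samples; 733 and 746 with quantile normalization), 2506 with the array set as a covariate (1189 higher, 1317 lower) and 1980 within the higher set. The 4681 genes without overlap, or 27.9%, compare with 10% by chance. Leaving out LC replicate 2 or 3, or CD1c DC replicate 1 or 2, gave 803, 858, 828 and 781 genes. The TGF-beta list also fell here (4 of 14, 0 rose, camera adjusted p = 0.00016, adjusted p = 0.075 with an estimated correlation). It did not pass between CD207 high cells and LC (adjusted p = 0.33), so it was not particular to lesion cells. Between CD207 high cells and CD1c DC, DC maturation genes (2 rose and 2 fell of 17, adjusted p = 0.52) and NF-kB targets (adjusted p = 0.34) did not pass. Their lower levels against LC were thus not seen against CD1c DC.

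Between sorts of the same lesions few genes could be told apart. CD207 was 5.34 ± 0.92 higher in CD207 high than in CD1a cells (17.53 ± 0.99 against 12.19 ± 3.74; adjusted p = 0.0079), and it was the 1 gene of 16768 that passed. The call held in 9 of 11 fits that each left out 1 donor, with adjusted p from 6.7e-05 to 0.26, with the array set as a covariate (5.49 ± 0.89; adjusted p = 0.0025) and within the higher set (4.93; adjusted p = 0.037). Within 7 donor pairs the difference in CD207 was 5.36 ± 0.99 and did not pass (adjusted p = 0.52; 5.30 ± 1.13 and adjusted p = 0.48 with the array set in the model). The 1 gene that passed within pairs was TCEAL1 (1.01 ± 0.08; adjusted p = 0.015), which did not pass over all samples (0.89 ± 0.34) or within pairs with the array set in the model (adjusted p = 0.080), and is named after its value was seen. Between CD207 high and low cells CD207 differed by 2.31 ± 0.81 and no gene passed (0 of 16768 in limma; 169 at an unadjusted p under 0.05). Paired within the 11 donors the count was also 0, with 1654 at an unadjusted p under 0.05 and a lowest adjusted p of 0.147. Chance gives about 5% of the 16768 genes at that unadjusted p. The paired fit gave more than this share and the fit without donor less. The counts of 0 therefore do not show that CD207 high and low cells are alike. CD207 low and CD1a cells gave 0 genes (324 at an unadjusted p under 0.05; 0 within 7 pairs, with 874). CXCR4 (-1.06), IFI30 (-1.21), CCL3 (-1.09), CLDN1 (1.18) and TYMS (0.66) were among the genes with the lowest p within donors, and did not pass.

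As lists, macrophage markers were lower in CD207 high than in CD207 low cells: the 14 genes had a median of -0.32 (adjusted p = 9.0e-16, and adjusted p = 0.0011 with an estimated correlation), among them the scavenger receptor CD163 (-0.93) and the glycoprotein GPNMB (-0.72). As single genes 0 of 14 passed in limma, over all genes or adjusted over the list alone, with 5 at an unadjusted p under 0.05. Osteoclast genes had a median of -0.23 (10 genes; adjusted p = 1.0e-06, and adjusted p = 0.016 with an estimated correlation), led by SPP1 (-1.46) and the protease CTSK (-1.25). Classical monocyte markers were lower as well (15 genes, median -0.22; adjusted p = 1.8e-05, and adjusted p = 0.27 with an estimated correlation). Within donors the estimated correlation gave adjusted p = 0.17 for macrophage and classical monocyte markers and adjusted p = 0.18 for osteoclast markers. Proliferation genes had a median of 0.25 (19 genes; adjusted p = 2.0e-09, and adjusted p = 0.27 with an estimated correlation), and LC markers a median of 0.27 (15 genes; adjusted p = 0.0016, and adjusted p = 0.35 with an estimated correlation). The LC list holds CD207, the gene that names these sorts (17.53 in the high and 15.22 in the low sort), so part of its shift follows from the sorting. In the comparison of CD207 high with CD1a cells 9 lists passed, and 0 with an estimated correlation.

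CD3 cells from the lesions served as a check of the sorts. CD207 high cells exceeded them in CD207 (10.38), PTGS2, the inducible cyclooxygenase (9.11), HPGDS (9.02), the Fc receptor chain FCER1G (8.93) and HLA-DQA2 (8.91). The costimulator ICOS fell by 8.43, CXCR4 fell by 6.97, the transcription factor ETS1 fell by 6.82, CTLA4 fell by 6.27 and PDE3B fell by 5.84. All 15 T cell markers fell (adjusted p = 8.7e-28) and 15 of 16 class II genes rose (adjusted p = 3.4e-21). MAPK/ERK output genes rose in 12 of 18 cases and fell in 1 (adjusted p = 5.5e-05), and these 3 lists passed with an estimated correlation as well (0.0019, 0.011 and 0.02). In total 5066 genes passed, 2623 higher and 2443 lower (limma, 11 against 10 samples), 5322 when paired within 10 donors, 6548 with the array set as a covariate, and 6100 and 1823 within the higher and lower set.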

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

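Single outlying samples were sought in the CD1a sort (n = 7) and the CD3 sort (n = 10) only, in 58 sets of values. Each set held 1 gene or 1 signature score in 1 of these sorts. Its highest and lowest value was compared with the nearest neighbour, by a test fixed before the data were examined. In 5 sets 1 sample stood apart, where chance alone gives about 5% of sets, so some of the 5 would stand out by chance. The sets share the same arrays and are not independent, so that 5% is a rough guide. CD3D in the CD1a sort (6.92 ± 1.74, n = 7) had a highest sample whose gap to the next made up 0.735 of the whole range. The pDC marker IL3RA in the CD1a sort (7.32 ± 0.68) had a gap of 0.801 of its range, again at the top. The small nucleolar RNA SNORD41 in the CD1a sort (5.32 ± 1.34) had a gap of 0.681 at the top. The CD1c DC score of the CD1a sort (6.37 ± 24.0%) had a gap of 0.658 at the top, for a signature of 3 genes. CD14 in the CD3 sort (4.99 ± 0.41, n = 10) had a gap of 0.754 at the top. No explanation was tested for these values.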

How the results depend on the processing

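The alternatives that use the array sets, the donor block together with the sets, the donor block in the signature fit and protein-coding genes alone were chosen after the data were seen; all others were planned. No named gene that passed in either fit reversed its direction in any of 14 settings. Of 1520 gene results, 1445 stayed on their side of the threshold with quantile normalization, 1433 with median centring and 1431 with the array set as a covariate, among them 15, 14 and 18 genes that passed in neither fit and changed sign. Unless stated, the cause was not tested. Median centring gave 1571, 1288 and 1123 genes for CD207 high, CD207 low and CD1a cells against CD1c DC, 438 for CD207 high cells against LC and 749 for LC against CD1c DC. Fits of 2 groups alone, with fewer samples behind the variances, gave 941 (CD1a against CD1c DC), 509 (LC against CD1c DC) and 0 (CD207 high against CD1a). Array weights gave 3461 for CD207 high cells against LC. A minimum difference of 1, stricter by construction, gave 1536, 1306 and 1209 against CD1c DC and 2152 against CD3. For CD207 high against CD1a cells, where 1 gene passed, quantile normalization gave 2, array weights 5, the array set as a covariate 3, donor as a random block 3 (74 with the set) and the paired block with the set 0. The paired block alone gave 1, TCEAL1 and not CD207. The array set as a covariate gave 3975, 3565 and 3535 genes against CD1c DC, 1475 for CD207 high cells against LC and 2506 for LC against CD1c DC, and with a random donor block 3990, 3583, 3611, 1482 and 2508. The higher set alone gave 1328 for CD207 high cells against LC. The lower set alone gave 836, 724 and 514 against its 1 CD1c DC array (with 1 CD1a array for 514), with the spread taken from other groups, and 1823 against CD3. Leaving out 1 sample or donor gave 1279 to 2750, 941 to 2232 and 842 to 1965 genes against CD1c DC, 374 to 799 for CD207 high cells against LC, 781 to 1240 for LC against CD1c DC, 4523 to 5171 against CD3, 0 to 5 for CD207 high against CD1a cells (CD207 not past the threshold without either of 2 of the 11 donors), and 0 to 0 for the other pairs of lesion sorts. Against CD1c DC the low ends came from CD1c DC replicates 1 and 2, and against LC from LC replicates 1 and 2. An estimated correlation left 3 lists against CD1c DC, 4 against LC and 2 between CD207 high and low cells. The CD1c DC score minus the CD14 monocyte score reversed with quantile normalization (6.44), with values adjusted for the array set (10.9; 8.80 with signatures from the 5 blood subsets) and as a correlation across genes on adjusted values (0.133); it also turned positive, past the threshold in neither fit, with a donor block in the signature fit (6.87). The difference from CD16 monocytes passed with quantile normalization (9.86), with adjusted values (11.2; 17.2 from the 5 blood subsets; 0.0810 as a correlation) with a donor block in the signature fit (9.11) and in 1 fit without a blood donor (5.51). The difference from CD141 DC no longer passed with quantile normalization (-3.29), as a correlation (-0.0633), with a donor block in the signature fit (-1.98), without a blood donor (-2.15) or a skin donor (-11.3), and reversed with adjusted values (3.21), but kept its direction and passed on adjusted values with signatures from the 5 blood subsets (-12.9) and as a correlation (-0.0625). The difference from pDC passed as a correlation (-0.117; -0.123 on adjusted values), and turned positive without passing with adjusted values (1.62; 3.86 from the 5 blood subsets) and a donor block in the signature fit (3.09). Reversed here means a change of sign where at least 1 of the 2 fits passed. Leaving out 1 donor gave -7.24 to -0.0578 for CD14, 3.10 to 5.53 for CD16, -12.9 to -2.15 for CD141, -2.64 to 1.71 for pDC and -72.2 to -66.8 for LC; the other left-out donors, and signatures from the 5 blood subsets on deposited values, left 0 CD1c DC genes and gave no value. The difference from LC passed in all 13 settings that gave one, with the limit from the build of the signatures given above. Array signal over background limits calls among low signals, since medians of 5.88 to 6.47 lay near the level of absent transcripts.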

Other observations

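The lists of cytokines, Notch signalling, transcription factors and lipid handling have not been described above. In CD207 high cells TNF rose by 5.53 ± 1.18 against blood CD1c DC (16.23 ± 1.37, n = 11, against 10.70 ± 1.97, n = 3; adjusted p = 0.00058) and IL18 by 3.57, while the cytokine OSM fell by 1.03 and EREG fell by 5.79; the list of 14 cytokines, with 3 higher and 2 lower, did not pass (adjusted p = 0.61). Of 10 Notch pathway genes 4 fell and 1 rose, led by the receptor NOTCH2 (-2.96 ± 0.40) and its target HES1 (-2.54 ± 0.42), with the ligand JAG2 higher by 0.58 (list adjusted p = 0.029, adjusted p = 0.085 with an estimated correlation and adjusted p = 0.065 with the array set as a covariate). Of 17 DC transcription factors 8 fell and 1 rose, with KLF2 (-1.79), ID2 (-1.87) and KLF4 (-1.24) as examples (adjusted p = 0.019, and adjusted p = 0.46 with an estimated correlation). Of 13 genes of cholesterol and lipid handling 4 fell, among them the fatty acid transporter CD36 (-2.16), the lipid droplet gene PLIN2 (-2.64) and the carrier FABP5 (-2.10) (adjusted p = 0.031, adjusted p = 0.28 with an estimated correlation and adjusted p = 0.065 with the array set as a covariate). NOTCH2 was also lower in epidermal LC than in CD1c DC (-3.06), and it did not differ past the threshold between CD207 high cells and LC (0.10 ± 0.40).

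Against epidermal LC, 0 of 19 proliferation genes passed in CD207 high cells (limma, 0 at an unadjusted p under 0.05; list adjusted p = 0.97), while single genes of arrest and survival did. CDKN2A, which encodes the cell cycle inhibitor p16, rose by 1.21 ± 0.25 (7.13 ± 0.58 against 5.92 ± 0.09; adjusted p = 0.0010) and by 1.30 ± 0.25 against CD1c DC. MDM2 rose by 2.15 and GADD45A fell by 2.35, and the senescence list did not pass (2 higher and 1 lower of 10; adjusted p = 0.68). Of 12 apoptosis regulators the inhibitors BCL2A1 (-2.99) and BIRC2 (-2.04) and the trigger PMAIP1 (-1.70) were lower and the effector BAX was higher by 0.93 (adjusted p = 0.038, adjusted p = 0.58 with an estimated correlation and adjusted p = 0.27 with the array set as a covariate). Type I interferon genes had a median of 0.78 (18 genes; adjusted p = 1.0e-04, and adjusted p = 0.58 with an estimated correlation), with IFI6 at 3.19 and OAS1 at 0.77, and 0 of 18 passed as single genes in limma (4 at an unadjusted p under 0.05). Inflammatory cytokines were lower (0 rose and 3 fell of 14; adjusted p = 0.0069, adjusted p = 0.22 with an estimated correlation and adjusted p = 0.052 with the array set as a covariate), with IL23A (-1.25) and IL6 (-1.17), and so were classical monocyte markers (0 and 4 of 15; adjusted p = 0.011, adjusted p = 0.58 with an estimated correlation and adjusted p = 0.052 with the array set as a covariate). Of 18 adhesion genes, with a median of -0.02, 0 rose and 5 fell over all genes, and 3 rose and 5 fell when adjusted over the list alone. The adhesion list passed downward (adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.22), with the array set as a covariate (adjusted p = 0.22) or in the higher set alone (adjusted p = 0.27).

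Of the tests of the 3 patterns below, those of CD2 and of keratinocyte RNA were chosen after the results were seen, and the test of T cell RNA replaced a weaker one that had been run. The others were written before their values were seen, and the splits of the samples were planned.

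Macrophage markers were lower in CD207 high than in CD207 low cells as a list, a call that did not pass within donors with an estimated correlation (adjusted p = 0.17), and classical monocyte markers, which share CD163 with the list, were lower too (median -0.22; adjusted p = 1.8e-05, and adjusted p = 0.27 with an estimated correlation). Against the array sets as the whole cause, the list passed within the higher set alone at the preset correlation (adjusted p = 2.4e-08), and with the set as a covariate and an estimated correlation (adjusted p = 0.011). Macrophage RNA carried into the CD207 low sort in shares that differ between donors predicts that the markers move together from donor to donor, and their within-donor differences had a median pairwise correlation of 0.328, where 1000 random sets had a median of -0.0026 and a 95th percentile of 0.0884. All 14 markers were lower in the mean (CD68 at 12.72 and 13.23, CD163 at 7.04 and 7.97 in the high and low sort), and the list mean was lower in 9 of 11 donors; the labels do not give the gates. Carry-over is a candidate explanation, monocyte RNA may contribute, and a range of states among the lesion cells themselves predicts the same and stays open, untested.

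CD2 was higher in CD207 high cells than in epidermal LC. It passed within the arrays with higher controls alone (adjusted p = 0.0018; 1.2e-06 with array weights and 0.064 in a fit of the 2 groups alone), which argues against the array sets. T cell RNA in the sort would need a share of 4.06% of the level of CD2 in the CD3 sort (14.17 ± 1.11), if the scale is linear after the log is undone. Over the 3 T cell markers with a predicted rise of at least 1, observed minus predicted differences had a median of -1.29. CD3D, for one, differed by 0.59 ± 0.76 where 2.22 was predicted. All 14 other T cell markers lay below their prediction, but that count is weak evidence. The share was set on CD2, the 1 marker of the list that rose, which favours shortfalls in the others. Some shortfalls also lay within the SE, as for UBASH3A (-0.0051, SE 0.23) and ZAP70 (-0.091, SE 0.17). Blood CD1c DC also carried CD2 (8.57 ± 0.72), so expression by the lesion cells themselves may be the source, as a hypothesis.

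The junction genes CDH1, EPCAM, CLDN1 and ALCAM were lower in CD207 high cells than in LC. Within the higher set alone 4 of these 4 genes passed, which argues against the array sets. Keratinocyte RNA in the LC samples cannot be told apart from expression by LC: between LC and CD1c DC the 8 keratinocyte markers differed by a median of 1.12 (SD 1.04, highest 2.95), against 4.48 (2.87 to 7.62) for the 4 genes, and no keratinocyte sample shows what ratio that RNA would bring. Keratinocyte markers were lower in the lesion cells as well, and the 3 LC arrays spread widely (CDH1 11.72 ± 2.49). A difference between epidermis and lesion tissue was not tested and stays open.

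Chance groupings of the samples were counted with the real split included. For CD207 high, CD207 low and CD1a cells against CD1c DC, CD207 high cells against LC and CD207 high cells against CD3, 1 of 100 splits, the real one, gave as many genes (2541, 2088, 1874, 741 and 5066 genes, highest other 760, 867, 753, 68 and 79). Other splits thus gave as many genes in a share under 0.05. Against healthy cells, the splits cannot separate cell type from disease, tissue or donors. LC against CD1c DC allows 10 splits, too few for a share under 0.05 (1329 genes, 1 split as large; highest other 77). For CD207 high and CD1a cells chance cannot be excluded across all samples (1 gene, 17 of 100 splits; highest other 6085). With a real count of 0 every split gives as many genes by construction, so the splits say nothing about chance between CD207 high and low cells (0 genes, 100 of 100 splits; highest other 2) and between CD207 low and CD1a cells (0 genes, 100 of 100; highest other 6591). The splits with 6085 and 6591 genes put 3 of the 4 arrays with lower controls into the smaller group, so these counts point to the array sets; within the higher set 1 gene passed for CD207 high against CD1a cells. With sorts swapped within donors, 1 of 100 splits, the real one, gave as many genes for CD207 high against CD3 (5322, highest other 0). For CD207 high against CD1a 1 of 64 such splits, the real one, gave as many genes (1, highest other 0), the smallest share that 64 splits allow. That count is the gene TCEAL1 and not CD207, and it was 0 with the array set in the model. A count of 1 gene that another setting loses leaves chance open. The swaps say nothing, again with real counts of 0, for CD207 low against CD1a (64 of 64; highest other 1) and CD207 high against low (100 of 100; highest other 1).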
